A study of Caenorhabditis elegans with 12 samples.

How the data were processed

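Total RNA of worms from 4 groups of 3 samples each was purified on columns, and 300 ng per sample was amplified, labelled with biotin and measured on an Affymetrix array. Per the submitters' processing notes, the arrays were handled with GCOS and the Affymetrix Expression Console and summarized with RMA, versions not given in the sources used here. RMA corrects background, quantile-normalizes the arrays and fits 1 value per probe set. The deposited values are log2 expression values, with array medians between 6.361 and 6.625. Quantile normalization assumes like distributions in all arrays, so a general loss of RNA in one group would not show. The deposited log2 columns were not identical in width, with an SD between 2.22 and 2.33.

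The table held 22625 probe sets. After 77 control probe sets were left out, 22548 were tested, with no filter on low values. Gene names came from the platform annotation: 20766 probe sets had 1 gene symbol, 887 several and 895 none. Of the single-symbol probe sets 20701 matched a gene of the RefSeq table for assembly WBcel235 through its gene number, and 0 symbols changed. That table was used for names only. A gene with several probe sets was represented by the one with the highest mean over all arrays, giving 17118 genes. Probe sets with the suffix _x_at (1227) or _s_at (5484) can detect related genes.

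Group means were fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), without a replicate block, so that all groups share one estimate of spread with 8 residual and 4.37 prior degrees of freedom. The comparisons were UV, TiO2 and UV+TiO2 against control, UV+TiO2 against UV and against TiO2, and the interaction, after a moderated F-test over the 4 groups. P-values were adjusted by Benjamini-Hochberg over all probe sets, with a threshold of 0.05. Camera tested 42 gene lists with a preset correlation of 0.01 on 1 probe set per gene, with Benjamini-Hochberg adjustment over the lists of a comparison. An estimated correlation and fry were run beside it. Fry asks whether a list's genes move one way on balance and does not compare a list with other genes. Rose and fell are used of a member with a limma adjusted p under the threshold.

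The groups, comparisons, lists, alternatives and the rule for named genes were set before the data were examined. The rule takes genes with 1 symbol: the 10 largest rises and 10 largest falls among those past the threshold with no overlap between arrays, for each comparison with control, and 5 and 5 for the other comparisons, without the condition on overlap for the interaction. Where fewer pass, all that pass are named and up to 5 each way with the smallest p are given as values that did not pass. Up to 4 members of each called list with the smallest p are added, and 18 sentinel genes, of which 17 were measured. Between 2 groups of 3 arrays chance gives no overlap in 10% of cases.

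The procedure was tested on simulated data with the same probe sets. For TiO2 against control, 92.5% of probe sets changed 2-fold and 59.7% of those changed 1.5-fold were called, with 12 calls among 22260 unchanged ones. For UV against control the shares were 89.6% and 68.7%, and for UV+TiO2 against control 95.5% and 62.7%. In each case both shifted lists and 0 of 40 other lists were called. Noise was drawn independently for each probe set, so this does not show how often lists of correlated genes are called by chance.

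Alternatives were a replicate block, a prior variance that follows the level with robust estimation, leaving out the 30% of probe sets with the lowest mean, quantile normalization again, centring on the median, array weights, 1 probe set per gene, only the 6 arrays compared, and each array left out in turn. The SD of each array's values as a covariate was added after seeing the data. Where an array was left out, its group kept 2 arrays and shared the spread of the others.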

Results

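Wild-type young adult hermaphrodites of the nematode Caenorhabditis elegans were kept for 24 h at 20 °C in a salt medium without food. They received ultraviolet light (UV), titanium dioxide (TiO2), both, or neither. Worms of the UV groups were irradiated for 4 h and then shared an incubator with the other groups for the remaining 20 h. The TiO2 dose is not stated in the sources used here. RNA levels were measured on 12 Affymetrix arrays, 3 for each of the 4 groups as log2 values, with array medians between 6.361 and 6.625. Nothing in the labels says that the 3 arrays of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision: a log2 difference between 2 groups had a median standard error (SE) of 0.12.

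UV separated the arrays and TiO2 did not. The first principal component held 84.8% of the variance and placed all 6 UV arrays opposite the 6 arrays without UV. Arrays of one group correlated at 0.987 to 0.998, arrays that differed only in TiO2 at 0.986 to 0.997, and arrays that differed in UV at 0.931 to 0.944. These correlations run across probe sets, which are not independent replicates. The second component held 6.71% of the variance and ran in part with the width of each array's distribution. Within the control group it set replicate 1 (SD of all values 2.33, score 28.53) apart from replicate 3 (SD 2.22, score −22.92). Control replicate 2, with an SD of 2.31, scored −9.48, so width does not account for all of it. By limma's moderated F-test, 12503 of 22548 probe sets (55.5%) differed among the 4 groups.

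**Figure D1:**
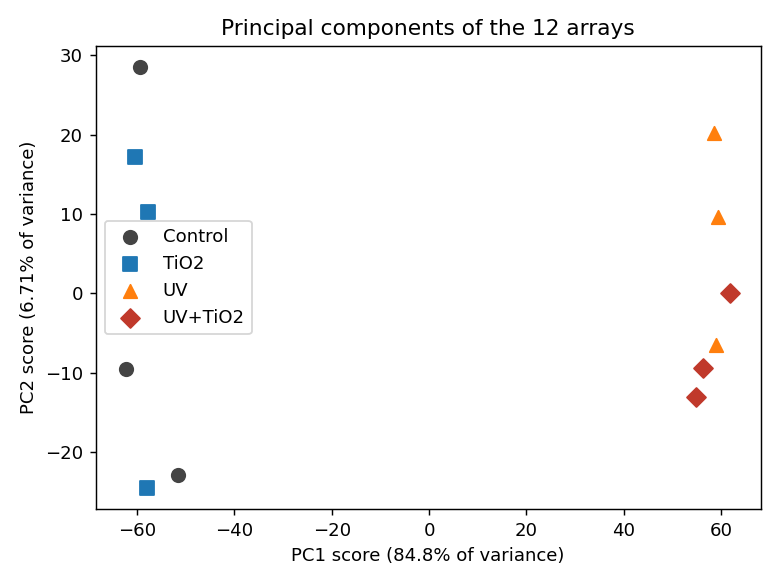
Scores of the 12 arrays on the first principal component (x axis, 84.8% of variance) and the second (y axis, 6.71% of variance), with 1 point per array and 3 arrays per group. UV and UV+TiO2 arrays lie to the right, control and TiO2 arrays to the left, and the 3 arrays of a group spread along the second component.

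The comparison of UV with control asks what UV alone did to the transcriptome. Genes of the cuticle were among the deepest falls. The collagen gene dpy-14 fell from a log2 value of 12.03 ± 0.22 (SD, n = 3) to 6.36 ± 0.19, and the cuticlin gene cut-3 from 11.62 ± 0.10 to 5.98 ± 0.21. The metallothionein gene mtl-1 fell from 10.64 ± 0.28 to 5.34 ± 0.49, which is 39.2-fold. The saposin-like antimicrobial gene spp-1 fell 28.9-fold. Also among the 10 largest falls were mtre-1 (log2 change −5.99, SE 0.12), scl-2 (−5.82, SE 0.09), F31F7.1 (−5.48), F53A9.8 (−5.15), the collagen gene col-74 (−5.02) and dod-3 (−4.89), a gene downstream of the insulin-signalling factor DAF-16. The ferritin gene ftn-1, a member of a called list, fell 22.6-fold. The largest rises were smaller. F59C12.4 rose 30.8-fold, from 7.06 ± 0.19 to 12.01 ± 0.07, and K09D9.1 rose 30.3-fold. The infection-response gene irg-2 rose 21.5-fold (log2 change 4.43, SE 0.16). C49G7.12 (4.74) and C49G7.10 (3.56), which by systematic name lie on the same cosmid as irg-2, rose too. The other genes with the largest rises were F22H10.2, Y58A7A.5, the F-box gene fbxc-58, the chondroitin proteoglycan gene cpg-9 and warf-1, with log2 changes of 3.50 to 4.27. For the 10 largest rises and the 10 largest falls the 3 UV arrays did not overlap the 3 control arrays, and limma's adjusted p ranged from 6.4e-13 for scl-2 to 1.1e-08 for fbxc-58.

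**Figure D2:**
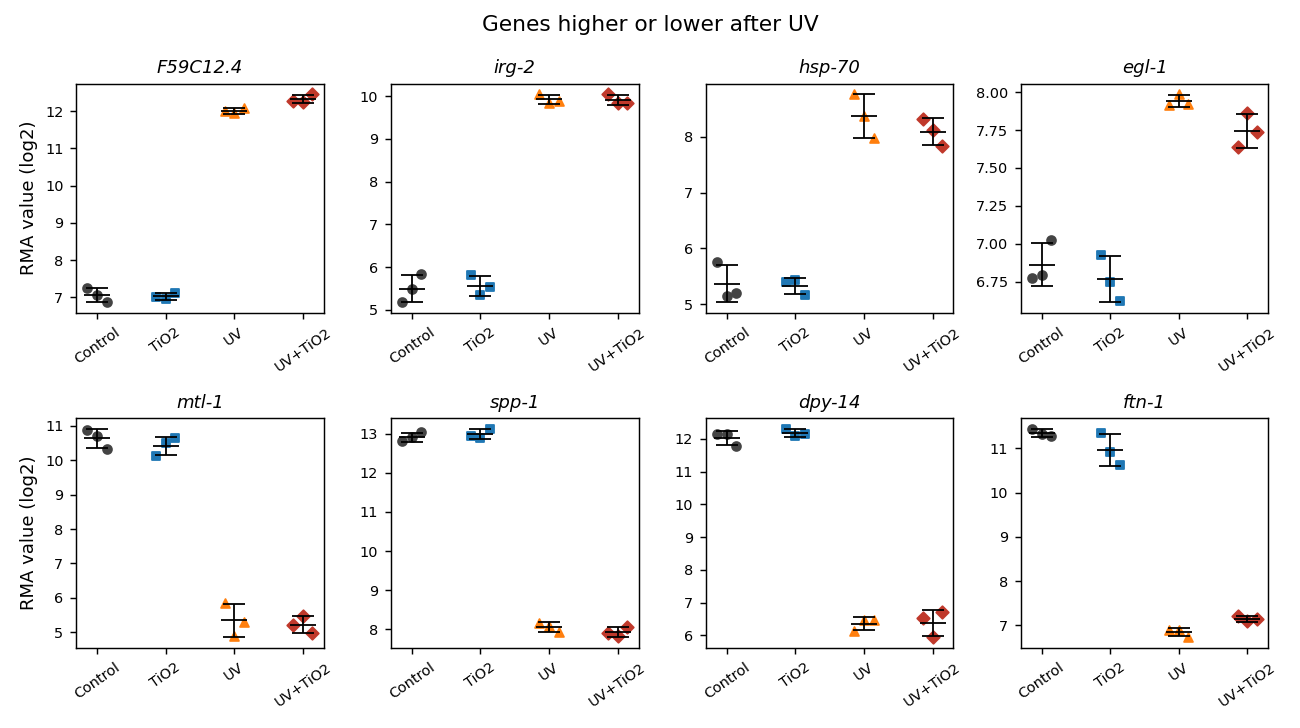
Log2 array values (y axis) of 8 genes in the 4 groups (x axis), with 1 point per array and the mean ± SD of 3 arrays in black. In the top row F59C12.4, irg-2, hsp-70 and egl-1 are higher in both UV groups, and in the bottom row mtl-1, spp-1, dpy-14 and ftn-1 are lower in both, while TiO2 arrays lie near the control arrays.

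Lists of differentiated somatic tissues were called downward after UV. Of 53 measured neuronal genes 42 fell and 2 rose (median log2 change −1.22), among them the neuropeptide genes flp-10 (−3.19), flp-16 (−3.24), flp-11 (−3.15) and pdf-1 (−2.42). Of 18 pharyngeal genes 16 fell and 1 rose (median −1.15), including phat-5 (−3.46), phat-2 (−2.92) and the troponin gene tnt-4 (−1.32). Camera's call for both lists held with an estimated correlation, with an adjusted p = 0.00529 for neurons and an adjusted p = 0.019 for pharynx. Of 21 intestinal genes 19 fell and 1 rose (median −1.33), including the intermediate filament gene ifb-2 (−2.97) and the protease gene asp-3 (−2.16). That call was lost with an estimated correlation (adjusted p = 0.0628). Of 24 body wall muscle genes 11 fell and 4 rose, with a median of −0.14 that turned to 0.04 when each array was centred on its median, and the falls included unc-54 (−0.77), which encodes a myosin heavy chain, and tni-1 (−1.28). The call was lost with an adjusted p = 0.49 under an estimated correlation. The counts were the same adjusted over the list alone, except that 2 pharyngeal genes rose. Beside these lists, 13 of 18 markers of late embryos and early larvae fell and 2 rose (median −0.814). Of 12 genes of the adult soma alone (cuticle collagens and vitellogenins), chosen after the results were seen, 8 rose and 3 fell (median 0.807).

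Stress-resistance and metabolic lists were called downward as well. Of 24 DAF-16 targets 17 fell and 1 rose (median −0.99), including mtl-1, dod-3, the catalase gene ctl-2 (−2.75) and dod-6 (−3.97). Of 15 targets of the hypoxia factor HIF-1, 11 fell and none rose (median −1.1), including ftn-1, cysl-1 (−2.14) and cysl-2 (−1.63). Both calls held with an estimated correlation (adjusted p = 0.019 for each). Fasting and lipid catabolism genes fell in 28 of 48 cases and rose in 4, with pck-1 (−2.04) and icl-1 (−1.40) among the falls. Lysosomal and vacuolar ATPase genes fell in 24 of 47 cases and rose in 7. Metal response genes fell in 10 of 20 cases and rose in 3. These 3 calls were lost with an estimated correlation (adjusted p = 0.071, 0.119 and 0.0628). Moulting genes fell in 23 of 43 cases and rose in 4, including the zona pellucida gene noah-1 (−3.65) and the protease inhibitor gene mlt-11 (−3.50), with an adjusted p = 0.0986 under an estimated correlation. The markers of late embryos and early larvae (median −0.814) fell in the same comparison as the DAF-16, HIF-1, moulting and other lists given here. Osmotic and cuticle-damage genes fell in 11 of 15 cases and rose in 2 (adjusted p = 0.066 with an estimated correlation). Fatty acid synthesis genes fell in 14 of 28 cases and rose in 7, and MAP kinase genes fell in 12 of 32 and rose in 6, the latter including jnk-1 (−2.98), and both calls were lost with an estimated correlation (adjusted p = 0.265 and 0.33). Adjusted over the list alone, 5 lipid catabolism genes and 3 osmotic response genes rose and 13 MAP kinase genes fell, and the other counts of genes were the same. With each array centred on its median, the falls and rises became 24 and 11 for lipid catabolism, 23 and 14 for lysosomes, 9 and 6 for metal response, 20 and 10 for moulting, 7 and 4 for osmotic response, 11 and 9 for fatty acid synthesis and 10 and 9 for MAP kinases, with medians still below 0.

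Some called lists were mixed. In the list of the endoplasmic reticulum stress response 13 of 29 genes fell and 5 rose, but the members with the smallest p were abu-8, abu-13, abu-14 and abu-15, genes of a family induced when that response is blocked, with log2 changes of −3.17 to −2.33, while the chaperone gene hsp-4 rose (0.47). Of 45 glutathione S-transferase genes 19 fell and 8 rose. The sentinel gst-4, a target of the oxidative stress factor SKN-1, rose (1.79). Of 74 antimicrobial peptide and lysozyme genes 33 fell and 10 rose, with spp-8 (−3.33), spp-18 (−3.65) and ilys-4 (−3.44) among the falls. Of 46 hypodermal genes 19 fell and 13 rose. These calls were lost with an estimated correlation (adjusted p = 0.247, 0.245, 0.245 and 0.539). When each array was centred on its median, the medians of these 4 lists turned from −0.17, −0.14, −0.09 and −0.02 to 0.01, 0.04, 0.09 and 0.16. Their counts were the same adjusted over the list alone.

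Lists of sperm, DNA repair, DNA damage and germline genes were called upward after UV, and none of these 4 calls held with an estimated correlation (adjusted p = 0.245, 0.542, 0.323 and 0.247). Of 80 sperm genes 58 rose and 5 fell (median 0.94), including ssp-34 (2.41), nspd-1 (2.16) and nspd-4 (2.38), while nspe-1 fell (−2.91). The probe sets of nspd-1 and nspd-4 carry the suffix of probes shared within a gene family, so their values may mix paralogs. Of 43 DNA repair genes 24 rose and 1 fell (median 0.55), including polh-1 (1.27), which encodes a translesion polymerase, exo-3 (1.08), dog-1 (1.01) and rpa-2 (0.65). Of 31 genes of DNA damage signalling and apoptosis 16 rose and 2 fell. The pro-apoptotic gene egl-1 rose (1.08, SE 0.10) and so did brd-1 (1.16). The nuclease gene nuc-1 (−2.25) and phg-1 (−1.60) were the 2 that fell. The recombinase gene rad-51 was lower (−0.28, adjusted p = 0.0184), a call that ended with median centring (0.299), with only the 6 arrays of both groups (0.0551), and without control replicate 1 (0.0712) or UV replicate 1 (0.0545). Of 36 germline genes 19 rose and none fell, including htp-3 (0.68) and wago-1 (0.91), and 29 rose with median centring. There were 59 sperm genes that rose and 6 that fell adjusted over the list alone, and 17 DNA damage genes that rose, with the other counts the same.

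Of 147 cuticle collagen genes 83 rose and 23 fell (median 0.44), so the list was called upward although its strongest members dpy-14, dpy-17 (−4.40), col-74 and col-165 (−4.35) fell. The adult collagen gene col-19 rose (1.13). Histone genes rose in 16 of 26 cases and fell in 6, with his-67 at 2.24 and his-71 at −2.55. Ribosomal protein genes rose in 19 of 75 cases and fell in 1, while median centring gave 65 and 0 and quantile normalization 13 and 4. All 3 calls were lost with an estimated correlation (adjusted p = 0.594, 0.711 and 0.452). Of the collagen genes 90 rose and 24 fell adjusted over the list alone, and likewise 18 histone genes and 11 ribosomal protein genes rose.

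**Figure D3:**
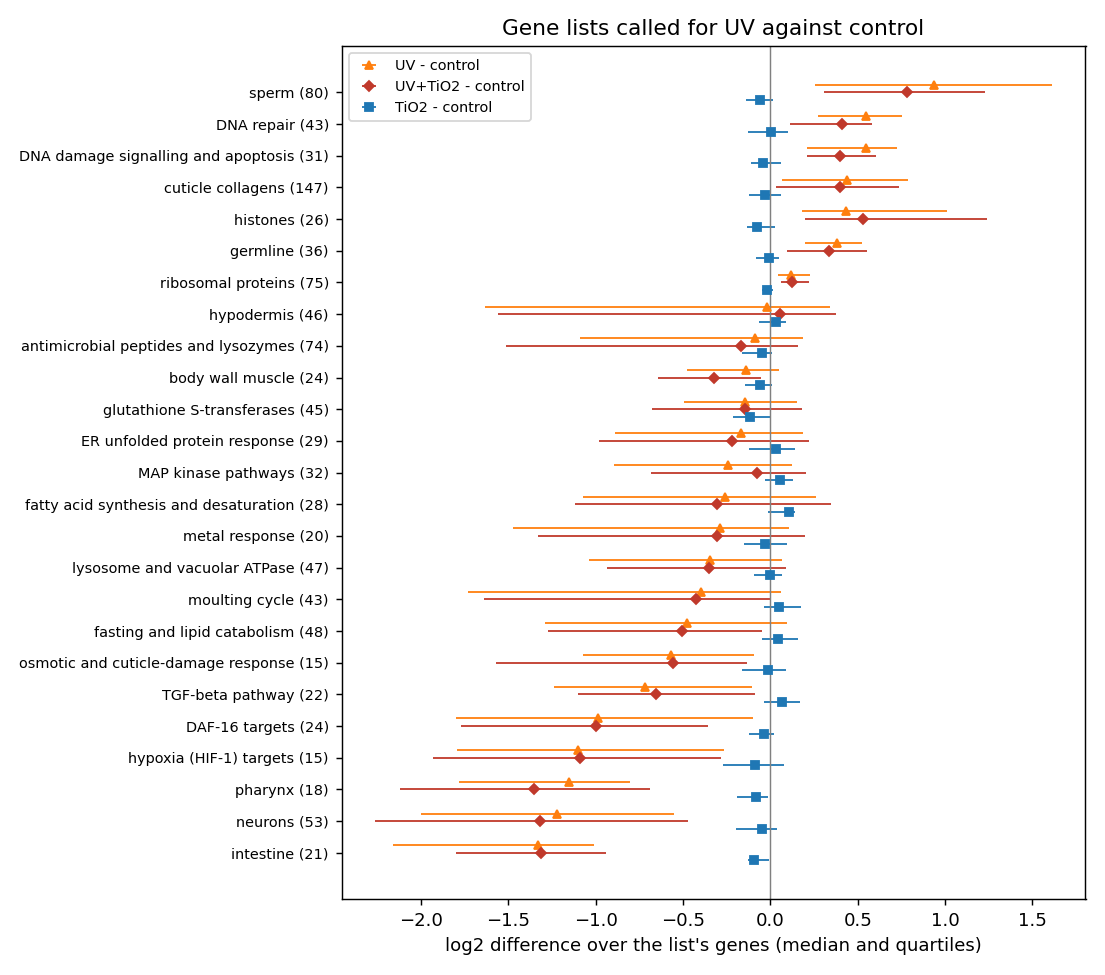
Median log2 difference from control (x axis), with quartiles as bars, over the genes of each list called for UV (y axis, number of measured genes in brackets), for UV, UV+TiO2 and TiO2. The UV and UV+TiO2 medians lie close together, from −1.33 to 0.94 for UV, while the TiO2 medians lie between −0.12 and 0.11, and the UV medians of 5 lists (endoplasmic reticulum stress, glutathione S-transferases, body wall muscle, hypodermis, antimicrobial) turn above 0 with median centring.

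Heat shock genes were split and camera did not call their list. hsp-70 rose 8.01-fold and the small heat shock gene hsp-16.2 rose 4.30-fold. Across the list 9 of 15 genes rose and 3 fell. The mitochondrial chaperone gene hsp-6 (0.24, adjusted p = 0.064), gcs-1 (−0.18, adjusted p = 0.103) and sod-3 (−0.01, adjusted p = 0.969) did not pass. hsp-6 passed with median centring (adjusted p = 0.00507), a prior variance that follows the level (0.0322) and the SD of each array as a covariate (0.0352), and its adjusted p was at most 0.184 in any alternative. gcs-1 passed with quantile normalization (0.00853), array weights (0.0484) and without control replicate 3 (0.0413), and its adjusted p was at most 0.984. The cytochrome P450 gene cyp-35A2 rose (2.02), the metallothionein gene mtl-2 fell (−1.47) and the yolk protein gene vit-2 fell (−0.64). TGF-beta and JAK/STAT were listed from prior knowledge of the study, not from its labels, so neither list is taken as an independent choice. Of 22 TGF-beta genes 14 fell and 1 rose (median −0.72), and 14 fell adjusted over the list alone. They included the nuclear receptor gene daf-12 (−2.26), the Smad gene sma-4 (−1.27), sma-9 (−1.92), daf-5 (−1.55), the ligand gene dbl-1 (−1.13) and sma-3 (−0.75). The call held with an estimated correlation (adjusted p = 0.019). Markers of late embryos and early larvae fell in the same comparison (median −0.814). Of 20 JAK/STAT genes 4 rose and 5 fell, the same numbers adjusted over the list alone, and the list was not called (camera adjusted p = 0.635). Its member sta-1 fell (−2.01, SE 0.28), from 6.58 ± 0.76 to 4.57 ± 0.08.

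In total 11414 probe sets (50.6%) passed for UV against control by limma, 6198 higher and 5216 lower. At least 2-fold differences were less even: 880 were higher and 2269 lower, and at 8-fold 19 were higher and 181 lower. The median over all probe sets lay 0.11 above control, and changes stand relative to that shift. With each array centred on its median, 12231 were higher and 4175 lower, so the share of higher calls moved from 54.3% to 74.6%. Of 1295 genes with more than 1 called probe set, 134 had probe sets that moved in opposite directions.

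The comparison of TiO2 with control asks what TiO2 did without UV, and a single gene passed. grl-21, a hedgehog-related gene, fell from 9.36 ± 0.03 to 8.76 ± 0.05 (log2 change −0.60, SE 0.07, limma adjusted p = 0.0394), with all 3 TiO2 arrays below all 3 control arrays. The genes with the next smallest p did not pass: dct-7 was at −1.04, hpo-26 at −0.79, irg-8 at −0.67, pqn-71 at −0.63 and F13B6.3 at −0.50, each with adjusted p = 0.181. On the other side lact-5 was at 0.65 and syg-2 at 0.54 (adjusted p = 0.181), cpg-24 at 0.55 (0.201), col-121 at 0.44 (0.205) and fbxb-101 at 0.56 (0.252). Of the 17 sentinel genes measured none passed: hsp-16.2 was at −0.27, hsp-70 at −0.04, gst-4 at 0.13, mtl-1 at −0.21, cyp-35A2 at 0.27 and egl-1 at −0.10, each with adjusted p = 1. At an unadjusted p under 0.05 there were 1027 probe sets (4.55%). The call of grl-21 ended in 11 of 15 alternatives, with adjusted p between 0.0137 and 1 and log2 changes between −0.65 and −0.57 across them. It also ended without any 1 of the UV or UV+TiO2 arrays, which enter only the shared spread (adjusted p between 0.108 and 0.144). The count was 0 without control replicate 1 or any 1 of the TiO2 replicates, and 4 without control replicate 2. With array weights it was 28, 4 higher and 24 lower. Of the genes above that did not pass, dct-7, hpo-26, irg-8, pqn-71, F13B6.3 and syg-2 then passed (limma adjusted p between 0.0234 and 0.0267).

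Camera called 11 lists for TiO2, all with medians close to 0. Glutathione S-transferases had a median of −0.12, with gst-12 (−0.51, adjusted p = 0.398) and gst-19 (−0.52, adjusted p = 0.47) at the front. Antimicrobial peptides had a median of −0.05, with fipr-26 (−0.68), cnc-4 (−0.45) and cnc-8 (−0.37), none of which passed. HIF-1 targets had a median of −0.09, with cysl-2 at −0.61 (adjusted p = 0.201). Fatty acid synthesis genes had a median of 0.11, with fat-7 at 0.53. The other 7 called lists were SKN-1 detoxification, antioxidant enzymes, body wall muscle, pharynx and oxidative phosphorylation, called downward, and moulting and lipid catabolism, called upward. No call held with an estimated correlation, where the smallest adjusted p = 0.236 belonged to the glutathione S-transferases. Adjusted over the list alone, 2 glutathione S-transferase, 2 SKN-1, 3 antimicrobial and 1 HIF-1 genes fell. The number of lists called was 5 without control replicate 2, 18 without control replicate 3 and 4 without TiO2 replicate 1. Neither the TGF-beta list (median 0.07) nor the JAK/STAT list (median 0.05) was called.

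Of the 25 lists that camera called for UV alone, 24 were called in the same direction for the joint exposure against control. The MAP kinase list was called for UV alone (camera adjusted p = 0.0171, and 0.0958 for the joint exposure) and the oocyte and eggshell list for the joint exposure (0.0339, and 0.0845 for UV). Both comparisons share the control arrays: with no group effect, 100 simulations on the residuals of the arrays gave a median of 2 and at most 14 lists called alike, and independent calls would give 1.33 upward and 7.29 downward. F59C12.4 rose 38.5-fold, C49G7.12 29.9-fold, K09D9.1 23.8-fold and irg-2 21.3-fold. mtre-1 fell 59.7-fold, scl-2 56.3-fold, dpy-14 49.7-fold and mtl-1 42.9-fold. Yolk protein gene vit-1 rose 12.7-fold, from 8.51 ± 0.30 to 12.18 ± 0.13. hsp-70 (2.72), hsp-16.2 (2.08), cyp-35A2 (1.82), gst-4 (1.31) and egl-1 (0.88) rose, and sta-1 (−2.07), dbl-1 (−0.86) and sma-3 (−0.45) fell. Of the neuronal genes 41 fell and 1 rose (median −1.32), of the pharyngeal genes 15 fell and 1 rose (median −1.35), and of the TGF-beta genes 14 fell and 1 rose (median −0.65). These calls held with an estimated correlation (adjusted p = 0.00485, 0.0155 and 0.0155), as did those of DAF-16 targets, HIF-1 targets, lipid catabolism, metal response and osmotic response. The other 17 calls were lost, with adjusted p from 0.059 for the intestine to 0.709, including oocyte and eggshell genes (adjusted p = 0.377). The hypodermis list was called downward with a median of 0.06 and a mean of −0.51, and the call was lost with an estimated correlation (adjusted p = 0.553). With quantile normalization that median was below 0. Adjusted over the list alone, 42 neuronal genes fell and 2 rose, and 2 TGF-beta genes rose. In total 12289 probe sets passed, 7197 higher and 5092 lower. Centring on the median gave 11811 and 4339, which moved the share of higher calls from 58.6% to 73.1%.

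Calls of the 2 comparisons overlapped. Of the probe sets called for UV and for UV+TiO2 against control, 5357 were higher in both, 4761 lower in both and 2 opposite. Independent lists of those sizes would share 1978 and 1178. Both comparisons use the same control arrays, which gives fold changes a correlation of 0.50 with no effect at all in simulated groups. The observed correlation was 0.978, with a covariance of 0.595 beside a simulated 0.00928. In the simulated groups the calls shared in one direction came to 0.01. Between UV against control and UV+TiO2 against TiO2, which share no arrays, 9551 of 9552 probe sets called in both moved the same way. These values argue against shared controls as the main source of the excess. With 3 control arrays no split of the controls was made, so part of it may still come from them.

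The effect of UV could be measured a second time, without shared arrays, in worms that had TiO2. Against TiO2 alone, UV+TiO2 raised F59C12.4 39.5-fold, C49G7.12 34.1-fold, K09D9.1 23.1-fold, irg-2 20.5-fold and fbxc-58 20.2-fold. It lowered mtre-1 59.5-fold, dpy-14 55.2-fold, scl-2 54.7-fold, cut-3 42.1-fold and F53A9.8 37.1-fold. Of the neuronal genes 41 fell and 2 rose, of the sperm genes 60 rose and 5 fell, and of the oocyte and eggshell genes 19 rose and 1 fell. The call of neurons held with an estimated correlation (adjusted p = 0.00567), and those of sperm and oocytes did not (adjusted p = 0.27 and 0.296). The counts adjusted over the list alone were 42 neuronal genes that fell, 3 that rose, and 61 sperm genes that rose. In total 12284 probe sets passed, 7282 higher and 5002 lower, while centring on the median gave 11577 higher and 4346 lower. Across all probe sets the UV effect without TiO2 correlated with that in its presence at r = 0.965 (slope 0.963), and of 9552 probe sets called in both 9551 moved the same way.

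The comparison of UV+TiO2 with UV asks what TiO2 added under UV, and here 8 of 74 antimicrobial peptide and lysozyme genes fell while the list's median stayed near 0 (−0.0042). nlp-29 fell from 8.81 ± 0.40 to 7.23 ± 0.27 (log2 change −1.58, SE 0.21, limma adjusted p = 0.0125), cnc-4 from 9.38 ± 0.16 to 7.92 ± 0.09 (−1.46, SE 0.10, adjusted p = 0.000108) and nlp-28 from 8.09 ± 0.51 to 6.63 ± 0.40 (−1.46, SE 0.23, adjusted p = 0.0379). These genes encode small peptides made in the epidermis in response to infection and wounding. F15E6.3 (−1.36) and dlc-2 (−1.3) completed the 5 largest falls. In all, 20 probe sets passed, each lower in UV+TiO2. Among them was grl-21 (−0.44, SE 0.07, adjusted p = 0.0459), named here after its values were seen, which also fell with TiO2 alone in a comparison that shares no arrays with this one. None of the 74 rose, and 15 fell adjusted over the list alone. All 8, picked for being lower, stayed lower with any 1 array left out. But 1 of them passed without UV replicate 1 or 2 or UV+TiO2 replicate 2 or 3, 4 without UV+TiO2 replicate 1 and 5 without TiO2 replicate 3. Besides the 3 above, nlp-30, nlp-33, cnc-8, fipr-21 and fipr-26 fell, with log2 changes of −1.12 to −0.63. Of these, nlp-30, nlp-33 and fipr-26 lie outside the rule for named genes in this comparison and were chosen after their values were seen. Only cnc-4 and cnc-8 of the 8 were measured by probe sets without a suffix for probes shared between genes. The sperm-family gene nspd-9 (−0.63) passed too. The list's mean was −0.17, and its call was lost with an estimated correlation (adjusted p = 0.28). In TiO2 against control, which shares no arrays with this comparison, all 8 genes were lower too. Their log2 changes ran from −0.07 for nlp-30 to −0.68 for fipr-26, and none passed. The median of the 8 was −0.411 there, beside −0.0493 over the 74 genes.

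**Figure D4:**
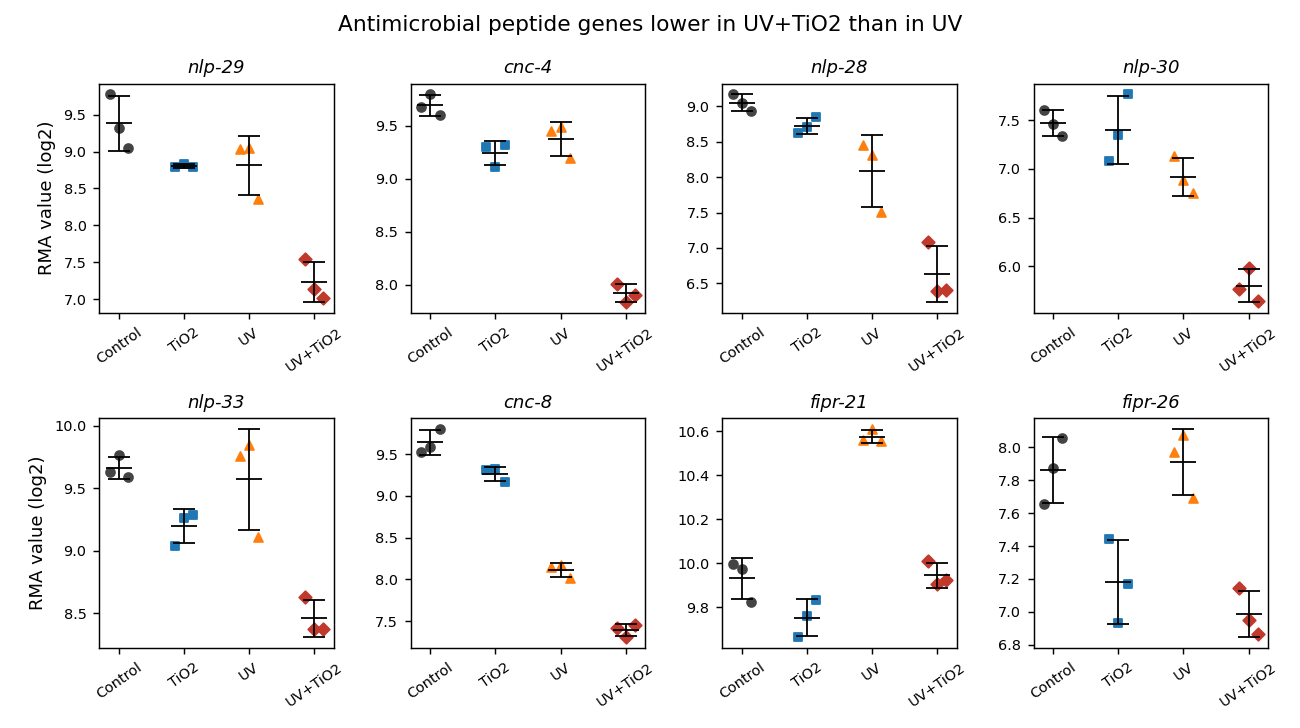
Log2 array values (y axis) of the 8 antimicrobial peptide genes that were lower in UV+TiO2 than in UV, in the 4 groups (x axis), with 1 point per array and the mean ± SD of 3 arrays in black. In every panel the 3 UV+TiO2 arrays lie below the 3 UV arrays, and for nlp-29 the means are 8.81 and 7.23.

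Other lists that camera called for UV+TiO2 against UV had small medians and lost the call with an estimated correlation, where the smallest adjusted p = 0.28. DNA repair genes had a median of −0.14, sperm genes −0.16, body wall muscle genes −0.13 and cuticle collagens −0.05, with col-91 at −0.56 and col-120 at −0.59, which did not pass. Intestinal genes had a median of 0.17, vitellogenins of 0.20 and MAP kinase genes of 0.11. SKN-1 detoxification genes had a median of −0.03, with gst-10 at −0.72 (adjusted p = 0.0634), DNA damage genes of −0.08 and neuronal genes of −0.06. Adjusted over the list alone, 6 collagen, 5 muscle, 5 SKN-1 and 1 sperm genes fell, and 2 intestinal, 1 vitellogenin and 1 MAP kinase genes rose. Genes nearest to passing upward were F57B9.3 (0.55, adjusted p = 0.078), B0403.3 (0.63, adjusted p = 0.0955), tent-5 (0.70), tag-120 (0.55) and F25B3.4 (0.43), the last 3 with adjusted p = 0.106. No sentinel gene passed. The count of 20 moved with single arrays: it was 2 without UV replicate 1, 2 without UV replicate 2, 69 without UV replicate 3, 9 without UV+TiO2 replicate 1, and 3 without UV+TiO2 replicate 2 or 3. All 20, picked for being lower, stayed so in each of these settings. Their median log2 change was −0.922 over all arrays and −0.907, −0.836, −1.02, −0.938, −0.866 and −0.924 in that order, while the median SE of 0.113 became 0.121 to 0.130. With array weights it was 1856, 978 higher and 878 lower, and with the SD of each array as a covariate 32.

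The interaction asks whether both exposures together differed from the sum of the single ones on the log2 scale. No probe set passed by limma (smallest adjusted p = 0.12), and 1162 (5.15%) had an unadjusted p under 0.05. With array weights 220 passed, and with a prior variance that follows the level 1 passed. The values nearest to passing were F23F12.12 (−1.11, adjusted p = 0.12), cnc-4 (−1.01, adjusted p = 0.143), F15E6.3 (−1.23), cpg-9 (−0.93) and nspd-9 (−0.66), the last 3 with adjusted p = 0.47. On the positive side T12D8.5 was at 0.82, fmo-2 at 0.72, srd-3 and vpat-1 at 0.65, and F13B6.3 at 0.52, none passing. With array weights cnc-4 passed (adjusted p = 0.0172), and over all alternatives its adjusted p ranged from 0.0172 to 0.741. In the antimicrobial list, which camera did not call, 4 genes had an interaction below 0 that passed adjusted over the list alone: cnc-4, cnc-3 (−0.79), nlp-30 (−1.05) and fipr-21 (−0.45), the last 3 named after their values were seen. That list passed fry's test for change in either direction (adjusted p = 0.0238) and did not pass its test for one direction on balance (adjusted p = 0.907). The former passed without control replicate 1, UV replicate 3, TiO2 replicate 1 or UV+TiO2 replicate 2 and not without any other array, where its adjusted p ranged from 0.0722 without control replicate 3 to 0.445 without UV replicate 2. The number passing over the list alone was 1 without UV replicate 1 or 2, 2 without UV+TiO2 replicate 3 and 10 without UV replicate 3. Of SKN-1 genes 2 were below 0 and 2 above adjusted over the list alone, of HIF-1 targets 1 and 1, and of moulting genes 1 was below. Camera called 3 lists, of which the intestinal one had a median interaction of 0.16, the sperm one −0.16 and the lipid catabolism one −0.09. None held with an estimated correlation (adjusted p = 0.976 for each). In these 3 lists 1 sperm and 1 lipid catabolism gene had an interaction below 0 that passed when adjusted over the list alone. The number of lists was 6 without control replicate 2 and 5 without control replicate 3, UV replicate 3, TiO2 replicate 1 or UV+TiO2 replicate 1. The TiO2 effects without and with UV correlated at r = 0.0723 across all probe sets, and at −0.168 without control replicate 1, −0.206 without TiO2 replicate 1, 0.264 without control replicate 3, 0.247 without TiO2 replicate 2 and 0.193 without TiO2 replicate 3.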

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

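The tests of adult somatic genes, of the kinds of probe set, of array width for the peptide genes and of the interaction over the peptide genes were chosen only after the result was seen. With 3 arrays per group no test for a single array apart from the others was made.

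There were 3 lists that stood out because the effect of TiO2 on them differed with UV in the preset camera test of the interaction. The median interaction was −0.155 for sperm genes, 0.159 for intestinal genes and −0.0854 for fasting and lipid catabolism genes. With an estimated correlation none was called (adjusted p = 0.976 for each), and fry called none.

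The fall of somatic genes in the UV arrays went with a fall of markers of late embryos and early larvae, a list written for this test. Their median log2 change was −0.814 (95% bootstrap interval over genes −1.68 to −0.478, 18 genes), with 13 falling and 2 rising, the hatching enzyme gene hch-1 at −4.01 (control mean 10.09) and hbl-1 at −4 (10.92), but the most abundant of them, egg-6 (11.16) and lin-26 (11.11), at 0.58 and 0.02. A candidate explanation is that arrays without UV hold RNA of late embryos or larvae that the irradiated worms lack. A list of genes transcribed by the embryo itself did not fall with them: 16 of 55 rose and 8 fell, with a median of 0.134. It also holds genes placed in the tissue lists here, such as hlh-1, elt-1, elt-3 and elt-7. The list thus marks no single stage and cannot decide the explanation. Lower somatic RNA in the adults themselves stays open: genes of the adult soma alone had a median of 0.807, with an interval of −0.192 to 1.68 over 12 genes, 8 rising and 3 falling. That list holds only cuticle collagens and vitellogenins, which moved apart. Its collagen genes all rose, from bli-2 (0.77) to col-38 (2.02). Of its vitellogenins vit-1 rose (3.38), vit-2 (−0.64), vit-5 (−0.27) and vit-6 (−0.47) fell, and vit-4 (−0.11) did not pass. A direct effect of UV on development, which the design names, was not tested apart from these.

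The fall of antimicrobial peptide genes in UV+TiO2 against UV covers 8 members. Cross-hybridization between paralogs cannot be told apart: 2 of the list's 43 members on plain probe sets and 6 of its 31 on suffixed ones were among the 8 (Fisher's exact test, two-sided, p = 0.0618), which so few members leave undecided. With the SD of each array as a covariate all 8 kept an adjusted p under 0.05, with a median log2 change of −1.01 beside −1.12. This argues against width, as the SD measures it, as the whole source of the fall. The 8 were picked by this same contrast, however. UV replicates 1 and 2 (SD 2.307 and 2.282) were also wider than UV replicate 3 (2.239) and the UV+TiO2 arrays (2.232 to 2.255). With quantile normalization again, which equalizes the widths, 6 of the 8 passed. Whether the fall needs UV cannot be told apart from a fall that adds to TiO2's own: fry gave a p of 0.000793 for the interaction over the 8 (median −0.826), but these were picked by part of the same contrast, and over the 74 genes of the list, a condition added once the first p was known, fry gave 0.342 with a median of 0.0188, while fry in either direction gave an adjusted p of 0.0238. Without UV replicate 1, 1 of the 8 passed, with a median log2 change of −1.02 (median SE 0.176) beside −1.12 (0.156) over all arrays. Without UV replicate 3 all 8 passed, with a median of −1.27 (0.138). Why calls ended was not tested, and the 8 were picked for their fall.

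Few probe sets passed for TiO2 alone. Width of the array distributions, as the SD measures it, is argued against as the reason by the covariate, with which again 1 passed. Other structure of the arrays is not covered by that. The first principal component of the deviations from group means held 50.2% of their variance and was not used as a covariate. Too few arrays for a 2-fold change was examined by the simulation, where 92.5% of such changes were called. Its noise was independent between probe sets, and many probe sets were changed at once, which loosens the adjusted threshold. With 1 call in the arrays themselves, it therefore cannot decide whether the arrays were too few. Smaller changes stay open as well, since 59.7% of 1.5-fold changes were called.

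For the 4 groups, 1 of 100 splits of the 12 arrays, the real one, gave as many as 12503 differing probe sets, and the highest other gave 1480. A random grouping of these arrays is thus argued against. A chance difference between cultures would give the same count if the arrays of a group came from 1 culture, so it is not excluded. For the interaction the real count of 0 is reached by all 100 splits whatever the data, so they decide nothing there, and the highest other gave 6461. Splits that mix UV and other arrays carry the UV effect into that contrast. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. For UV against control 1 split of 10 reached the real 11414 (highest other 0), for UV+TiO2 against control 1 reached 12289 (highest other 0), for UV+TiO2 against UV 1 reached 20 (highest other 0) and for UV+TiO2 against TiO2 1 reached 12284 (highest other 0). For TiO2 against control 2 of 10 reached the real 1, and the highest other called 3528. That split set control replicate 1 with TiO2 replicates 2 and 3, whose SDs were 2.327, 2.319 and 2.297, against arrays with SDs of 2.307, 2.223 and 2.23, which points to a structure of the arrays that follows the second principal component and not TiO2.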

How the results depend on the processing

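The SD of each array as a covariate was chosen after seeing the data. Counts for the 4 groups, for UV and UV+TiO2 against control and for UV+TiO2 against TiO2 stayed within 1.5 times under every alternative run, and UV's effect without and with TiO2 correlated at 0.941 to 0.972 with an array left out. With a replicate block 11162 probe sets passed for UV, 11953 for UV+TiO2 against control, 17 for UV+TiO2 against UV and 0 for TiO2, and no other count of probe sets or lists changed by over 1.5 times. Of the 20 lower in UV+TiO2 than UV, 15 passed with it, and of the 8 peptide genes 5, and the antimicrobial list's fry p for the interaction in either direction rose from 0.0238 to 0.0656. The replicate numbers do not pair the arrays: deviations of same-numbered arrays correlated at −0.714 to 0.501, 8 of 18 above 0.1, and 3 of 12 arrays correlated best with their own number. The count of 1 for TiO2 became 0 with the block, the prior by level, the dimmest 30% left out, quantile normalization, median centring and only 6 arrays, 28 with array weights, and 0 to 4 with an array left out. grl-21 had an adjusted p of 0.0137 to 1 and a log2 change of −0.65 to −0.57 across these. For UV+TiO2 against UV array weights gave 1856, the SD covariate 32, and an array left out 2 to 69. All 20 were lower in each of 18 settings, but they were picked for being lower, so that is weak evidence. Their median log2 change was −1.04 to −0.836, and the number still passing ranged from 2 to 20. The block, the prior by level and leaving out a control or TiO2 array cannot change that median (−0.922). For the interaction array weights gave 220 and the prior by level 1. The TiO2 effects without and with UV correlated at −0.206 to 0.264 with an array left out, below 0 without TiO2 replicate 1 (−0.206) and control replicate 1 (−0.168). Lists called fell with an estimated correlation from 25 to 5 for UV, from 25 to 8 for UV+TiO2 against control and from 26 to 8 for UV+TiO2 against TiO2. They fell to 0 for TiO2, UV+TiO2 against UV and the interaction, where fry for one direction on balance also gave 0. Fry for change in either direction gave 4, 6 and 1 lists in these 3 comparisons. Where UV differed, fry for one direction on balance gave more lists than camera. It gave 33 for UV, 36 for UV+TiO2 against control and 35 for UV+TiO2 against TiO2, without comparing a list with other genes. For TiO2, 11 lists became 6 with quantile normalization, 3 with the SD covariate and 4 to 18 with an array left out. For the interaction, 3 lists became 5 without the dimmest 30% and 2 to 6 with an array left out. The cause was not tested, except that fewer arrays leave fewer degrees of freedom. Of 120 named genes called for UV, 1 lost its call under some setting and 0 reversed. Of 8 called for UV+TiO2 against UV, 7 did. Signal over background is not given by these values and was not analysed here.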

Other observations

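Cytochrome P450 genes went both ways after UV: of 73 measured 15 rose and 19 fell, while with each array centred on its median 34 rose and 12 fell. UDP-glucuronosyltransferase genes rose in 23 of 64 cases and fell in 17 (32 and 14 with centring), and C-type lectin genes rose in 53 of 220 cases and fell in 44, which centring on the median turned into 142 and 38. Genes transcribed by the embryo itself rose in 16 of 55 cases and fell in 8 (32 and 7 with centring). Oocyte and eggshell genes rose in 14 of 29 and fell in 3 (20 and 1). Proteasome genes rose in 9 of 35 cases and fell in 4 (19 and 0 with centring), and oxidative phosphorylation genes rose in 20 of 57 and fell in 9 (31 and 4). Of 43 genes for light and hydrogen peroxide sensing 4 rose and 3 fell, but 27 rose and 2 fell with median centring. Of 5 vitellogenins vit-1 rose (3.38), while vit-2 (−0.64), vit-5 (−0.27) and vit-6 (−0.47) fell. Camera called none of these lists for UV against control.

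Of 30 antioxidant enzyme genes 11 rose and 8 fell after UV, of 23 SKN-1 detoxification genes 7 rose and 7 fell, of 14 genes of the mitochondrial stress response 6 rose and 4 fell, and of 26 PMK-1 immunity genes 9 rose and 6 fell. With centring these became 14 and 7, 9 and 6, 8 and 2, and 14 and 6. Endocytosis genes fell in 19 of 52 cases and rose in 10, and Wnt pathway genes fell in 13 of 29 and rose in 8, with medians that turned above 0 when each array was centred on its median. Camera called none of these lists for UV. Fry, which does not compare a list with other genes, passed the antioxidant (adjusted p = 1.28e-05), Wnt (4.65e-05), endocytosis (0.000317) and SKN-1 (0.0196) lists. It did not pass the mitochondrial (0.283) or PMK-1 (0.0614) list.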
